A study of Mus musculus with 12 samples.

How the data were processed

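RNA was sequenced from 4T1 mouse mammary carcinoma cells carrying Cop1 sgRNA1, Cop1 sgRNA2 or a Rosa26 control guide, after vehicle or IFNγ at 20 ng/ml for 24 hours, with 2 libraries in each of the 6 groups. Per the labels' protocols, libraries were made with an Illumina TruSeq RNA kit from total RNA extracted with a QIAGEN kit. Per the submitters' processing notes, the tools used were STAR 2.4.0, HTSeq (version not stated) and DESeq2 1.10, with the genome build mm10. The deposited table holds the authors' whole-number gene counts per library, not normalized, for all 12 libraries in 1 table. The strand setting of the counting, the gene annotation and the treatment of reads that align to several genes are not given in the sources used here. Without them, reads of overlapping genes and of members of multigene families cannot be assigned with certainty. Columns of other samples numbered 0.

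The table named 22298 genes, of which 5858 had no count in any library. A row of totals was left out of library sizes and tests. It equalled the sum of the gene counts in 11 libraries (100% of the gene counts) and exceeded it by 360 counts in Cop1_sgRNA1 vehicle replicate 1. Gene names of 4 rows were the same 2 date-like strings, as spreadsheet software makes from gene symbols, and no such row is named here. Totals per library lay between 19378070 and 32609717 counts. A group with no count of a gene was given a floor of 3 counts over the group for any fold, and ratios from 1 to 3 counts carry an exact 95% counting interval. Intervals and floors cover counting error only, since the reads carry no molecular identifiers.

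Replicates were compared before use. The counts of the 2 libraries of a group differed by more than sampling noise in all 6 groups, with a chi-square per degree of freedom of 2.33 to 4.21 over genes with at least 10 counts in the pair, so no pair looked like 1 library deposited again, and each library entered the model on its own. This does not tell whether the libraries came from separate cultures. The coefficient of variation between replicates beyond counting noise was 3.21% (common dispersion 0.00103), which is small, and calls therefore include many small changes.

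Differences were tested with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood F test with TMM normalization, robust empirical Bayes and 1 model with a mean for each of the 6 groups, so that all groups share the estimate of the spread (6 residual degrees of freedom, median prior 34.5). The low-count filter filterByExpr (minimum count 10, minimum total 15) left 11904 genes. Removed genes held at most 0.0267% of a library's counts. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in a comparison. Comparisons were Cop1 loss against Rosa26 in vehicle and with IFNγ, where Cop1 loss is the mean of the guides, IFNγ against vehicle in Rosa26 and in Cop1-loss cells, and the difference between these responses (the interaction). Group levels are given as mean CPM ± SD of 2 libraries, from counts and TMM-scaled library sizes, and log2 changes with their standard error.

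The groups, comparisons, gene lists and alternatives were fixed before the data were examined, as was the rule for naming genes. In each comparison the rule takes Cop1, the 6 largest increases and 6 largest decreases among called genes with a mean log2 CPM of at least 3 and the same sign in both guides, the 3 called members of each list with the smallest p, 2 members of a discussed list without a call, and a set of genes of interest such as Ccl2, Csf1, Cebpd, Jun and Cxcl10. The 28 gene lists cover interferon responses, antigen presentation, chemokines, COP1 substrates and their targets, stress, growth, epithelial and mesenchymal genes, and markers of other cell types. Some genes, such as Jun, Cebpb, Cebpd and Cxcl1, are on several lists, so results of different lists are not independent. Each list was tested with camera (limma 3.58.1) at its preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Camera values are those of the preset correlation unless stated, and for strongly called lists the estimated one gave much larger p-values. Counts of list members cover only members that passed the low-count filter, for example 4 of 18 leukocyte markers. Overlaps and correlations of the guides, which share the Rosa26 libraries, are given beside values from 20 simulations of unchanged groups, which hold no difference between cell populations.

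The model code was tested on simulated counts with 200 changed genes, 50 at each of 1.25, 1.5, 2 and 4-fold. For Cop1 loss in vehicle (11745 genes run) it recovered 68%, 82%, 90% and 100% of these, and 6.59% of calls were false. For Cop1 loss with IFNγ (11739 genes) the shares were 58%, 84%, 90% and 98%, with 7.82% false. For IFNγ in Rosa26 cells (11749 genes) they were 64%, 84%, 90% and 96%, with 3.47% false, and for IFNγ in Cop1-loss cells (11747 genes) 62%, 90%, 94% and 98%, with 10.9% false. For the interaction (11737 genes) they were 54%, 78%, 80% and 92%, with 6.17% false. Except for IFNγ in Rosa26 cells, the false share was above the threshold of 0.05. The simulated changes were fewer than the calls in the data and the same in both guides, with no difference between cell populations. These shares therefore may not hold for the data.

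Alternatives were DESeq2 1.42.0 and limma-voom as tests, DESeq2 size factors and upper quartile scaling, no low-count filter and a stricter one (CPM over 1 in 4 libraries), the replicate number as a block, no robust estimation, a test against 1.5-fold (glmTreat), only the compared groups in the model, the Cop1 libraries of a treatment as 1 group, and leaving out each library in turn. Where that left a group with 1 library, it was assumed to vary like the other groups. Summing the 2 libraries of each cell population and treatment was added after the data were seen. It leaves Rosa26 with 1 column per treatment, so that its spread comes from the guides alone. Gene positions and exon numbers are from the GENCODE M21 annotation of GRCm38, the assembly also called mm10. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.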

Results

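Gene expression was measured by RNA sequencing in 4T1 cells, a BALB/c mouse mammary carcinoma line used as a model of triple-negative breast cancer. The cells carried a guide RNA against Cop1, either sgRNA1 or sgRNA2, or a control guide against Rosa26, a locus commonly targeted as a neutral site. Each population received vehicle or interferon gamma (IFNγ) at 20 ng/ml for 24 hours. Cop1 encodes an E3 ubiquitin ligase whose textbook substrates include the transcription factors c-Jun, C/EBP and ETS family members, and IFNγ is a cytokine that signals through JAK kinases. The design asks how loss of Cop1 alters transcription in 4T1 cells at rest and under IFNγ. The 6 groups held 2 libraries each, with gene count totals from 19378070 to 32609717 over the 12 libraries. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. IFNγ and vehicle libraries separated along the first principal component of log2 CPM, which held 59.2% of the variance, and Cop1-guide and Rosa26 libraries along the second, with 15.9%.

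Cop1 mRNA was lower with both guides and in both treatments. Cop1 is a protein-coding gene on chromosome 1, from 159232320 to 159347640 on the plus strand of GRCm38, with 20 exons in its principal transcript. In vehicle, Rosa26 cells had 94.0 ± 6.0 CPM (counts relative to the TMM-scaled library total; SD, n = 2), sgRNA1 cells 61.1 ± 2.83 and sgRNA2 cells 34.6 ± 0.204, so that sgRNA1 left 64.9% and sgRNA2 36.8% of the Rosa26 level. With IFNγ the same groups had 81.9 ± 2.07, 60.4 ± 0.388 and 33 ± 0.935 CPM. Averaged over the guides, the log2 change against Rosa26 was -1.03 ± 0.048 in vehicle (standard error, as after every log2 change here; adjusted p = 6.01e-21) and -0.88 ± 0.05 with IFNγ (adjusted p = 2.34e-18), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The guides differed from each other, with sgRNA2 lower by -0.82 ± 0.062 in vehicle (adjusted p = 7.51e-13) and by -0.88 ± 0.063 with IFNγ (adjusted p = 1.28e-13). IFNγ itself lowered Cop1 slightly in Rosa26 cells (-0.20 ± 0.054, adjusted p = 0.00361), a call that ended without Rosa26 vehicle replicate 2 (adjusted p = 0.144) or Rosa26 IFNγ replicate 1 (adjusted p = 0.0602), with 0.000522 to 1 over all alternatives. The sources used here give neither where in Cop1 the guides cut nor whether the populations were pools or clones, and mRNA does not measure the remaining protein. With the 2 libraries of each population summed, an alternative added after the data were seen, so that Rosa26 has 1 column per treatment and the spread comes from the 2 guides alone, the decreases were -0.97 (adjusted p = 0.342) and -0.81 (adjusted p = 0.395), the highest p over the alternatives, whose lowest were 2.24e-94 and 6.89e-65.

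**Figure D1:**
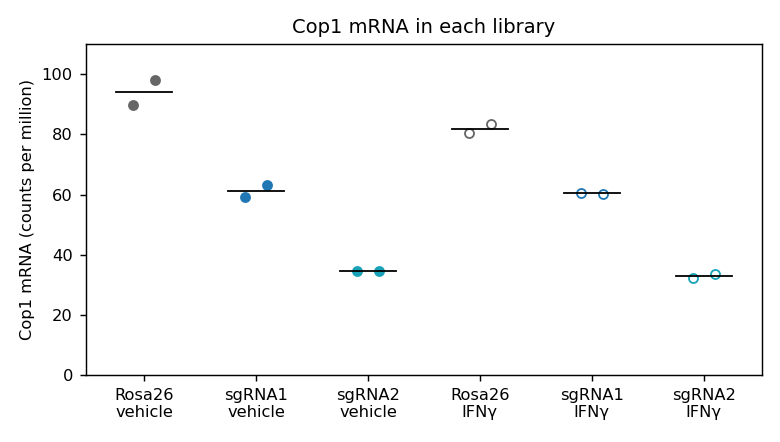
Cop1 mRNA in CPM (vertical axis) in each of the 12 libraries, by group; points are libraries and bars the means of 2. Rosa26 libraries lay between 80.4 and 98.2, sgRNA1 libraries between 59.1 and 63.1 and sgRNA2 libraries between 32.3 and 34.7.

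Loss of Cop1 in vehicle was accompanied by lower transcripts of interferon-stimulated genes and of the CXCR3 ligand Cxcl10, and by higher transcripts of several AP-1 and ERK pathway genes. Isg15, a ubiquitin-like interferon-stimulated protein, fell from 19.2 ± 0.324 CPM in Rosa26 cells to 7.61 ± 1.86 with sgRNA1 and 11.4 ± 0.241 with sgRNA2 (SD, n = 2), a log2 change of -1.03 ± 0.09. Cxcl10 (chromosome 5, 92346638 to 92348889), which draws CXCR3-bearing lymphocytes, fell by 1.80 ± 0.14 on the log2 scale. Plau (chromosome 14, 20836660 to 20843385), the urokinase-type plasminogen activator, rose from 159 ± 1.87 CPM to 625 ± 17.5 and 481 ± 22.5, a log2 change of 1.79 ± 0.03 (adjusted p = 1.24e-36). The transcription factor gene Tfap2c (chromosome 2, 172549593 to 172558622) had the largest increase among genes averaging a log2 CPM of at least 3, at 2.4 ± 0.15. Of 11904 genes tested, edgeR's quasi-likelihood test called 4258 (1976 higher, 2282 lower), and 273 of these changed at least 2-fold.

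Of 23 tested type I interferon-stimulated genes, 20 fell in vehicle (21 adjusted over the list alone; camera, adjusted p = 6.76e-11), among them Parp14 (-0.83 ± 0.07). Their median log2 change was -0.84, or -0.83 with the 1 member that had at most 3 counts in a group set to the bound of the detection floor. Among guanylate-binding proteins and other immunity GTPases, which act against intracellular pathogens, 11 of 16 fell (11 adjusted over the list alone; camera, adjusted p = 0.00402), including Irgm1 (-0.62 ± 0.10) and Gbp3 (-0.78 ± 0.09). Gbp5 (-1.99 ± 0.44) was close to the detection limit, with 29 counts over both Rosa26 libraries, 11 with sgRNA1 and 5 with sgRNA2. These genes belong to multigene families, and how the authors' counting divided reads between their members is not stated. Of the 4 tested among 11 listed CXCR3 ligands and lymphocyte chemokines, 3 fell (3 adjusted over the list alone; camera, adjusted p = 6.87e-07, and adjusted p = 0.0153 with an estimated correlation), among them Cxcl16 (-0.83 ± 0.03). The CXCR3 ligand Cxcl9 was near the detection limit, with 2 counts over both Rosa26 vehicle libraries. Of 18 IFN signalling and feedback genes, 3 rose and 8 fell (3 and 10 adjusted over the list alone) with no call for the list (camera, adjusted p = 0.5). There, the transcription factor gene Irf8 rose by 1.04 ± 0.06. Of 19 genes of MHC class I presentation, 5 rose and 6 fell (5 and 6 adjusted over the list alone; camera, adjusted p = 0.304), with Tapbp at -0.39 ± 0.03 and B2m at 0.11 ± 0.02.

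Chemokines for myeloid cells moved in both directions in Cop1-loss vehicle cells. Of 13 monocyte and macrophage attractants, 3 rose and 7 fell (3 and 8 adjusted over the list alone; camera, adjusted p = 0.0824). Without Rosa26 vehicle replicate 1, or without replicate 2, 6 of the 13 were called. Spp1, which encodes osteopontin, fell (-0.62 ± 0.03) and Csf1, the macrophage growth factor, fell by 0.28 ± 0.03, while Cx3cl1 rose (0.98 ± 0.05). Ccl2 (chromosome 11, 82035571 to 82037453), which recruits monocytes, was at -0.45 ± 0.17 and was not called (adjusted p = 0.0857). Its sgRNA1 libraries lay apart (16.8 ± 5.95 CPM, SD, n = 2). Without Cop1_sgRNA1 vehicle replicate 1, Ccl2 was at -0.26 (adjusted p = 0.0035), and without replicate 2 at -0.63 (adjusted p = 1.08e-09), with 1.08e-09 to 1 over all alternatives. Of 9 neutrophil attractants, 3 rose and 3 fell (3 and 3 adjusted over the list alone), and the list was called lower (camera, adjusted p = 0.000533), with Cxcl5 at -0.96 ± 0.02 and Cxcl3 at -1.56 ± 0.10. The highest change on this list was 1.16. Cxcl1 was higher with both guides, at 355 and 344 CPM with sgRNA1 and 335 and 314 with sgRNA2 against 290 and 301 in the Rosa26 libraries. Of 13 checkpoint and immune-evasion genes, 2 rose and 4 fell (2 and 4 adjusted over the list alone; camera, adjusted p = 0.0651). Nos2, the inducible nitric oxide synthase (-0.82 ± 0.05), and Ptgs2, which encodes cyclooxygenase-2 (-0.51 ± 0.02), were among the lower ones. Of 4 fibroblast and endothelial markers 3 fell (3 adjusted over the list alone; camera, adjusted p = 0.168), 1 without Rosa26 vehicle replicate 2, with the matrix gene Postn at 4.75 ± 0.0151 CPM in Rosa26 cells against 1.17 ± 0.125 and 2.41 ± 0.0832. Of 4 leukocyte markers 2 fell (2 adjusted over the list alone; camera, adjusted p = 0.304), 1 without Rosa26 vehicle replicate 1 or 2, Cop1_sgRNA1 vehicle replicate 1 or Cop1_sgRNA2 vehicle replicate 1.

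Transcripts tied to known COP1 substrates moved in different directions in vehicle. Of 14 C/EBP and acute-phase genes, 3 rose and 6 fell (3 and 6 adjusted over the list alone), and the list was called lower (camera, adjusted p = 0.000397). Cebpd (chromosome 16, 15887286 to 15891031; -1.02 ± 0.08), Cebpb (-0.63 ± 0.05) and complement C3 (-0.98 ± 0.03) fell. Of 22 AP-1 members and targets, 12 rose and 4 fell (13 and 4 adjusted over the list alone; camera, adjusted p = 6.76e-11), including the protease gene Mmp3 (0.80 ± 0.03), the EGF receptor ligand Hbegf (0.78 ± 0.03) and Jun (0.34 ± 0.04). Of 23 genes of ERK and ETS output, 11 rose and 4 fell (11 and 4 adjusted over the list alone; camera, adjusted p = 0.00417), with the ERK phosphatase Dusp6 at 0.74 ± 0.03 and Ccnd1, which encodes cyclin D1, at 0.33 ± 0.02. Among 25 genes of COP1 substrates, adaptors and ligase partners, 5 rose and 11 fell (5 and 11 adjusted over the list alone; camera, adjusted p = 0.047, and adjusted p = 0.125 with an estimated correlation). Of these, the pseudokinase Trib2 rose (0.60 ± 0.07), while Trib3 (-1.26 ± 0.07) and Ets2 (-0.70 ± 0.04) fell. Of 21 genes of the integrated stress response and unfolded protein response, 14 fell and 2 rose (15 and 3 adjusted over the list alone; camera, adjusted p = 7.57e-12), with Chac1, which degrades glutathione, at -1.39 ± 0.07 and Nupr1 at -1.05 ± 0.07. Of 23 NF-kB targets, 3 rose and 10 fell (3 and 13 adjusted over the list alone; camera, adjusted p = 0.0612). Of 28 lists, camera called 12 in vehicle with a preset correlation, and 9 of these held with an estimated one. The guides called 2597 genes in the same direction each on its own, 1198 higher against 253 expected for independent lists and 1399 lower against 329 expected, and 11 in opposite directions. The guides share the Rosa26 libraries, and 20 simulations of unchanged groups against them gave at most 2 genes higher and 3 lower with both. The simulations held only the spread between libraries of a group and no difference between cell populations. They therefore cannot separate loss of Cop1 from a property of the Rosa26 population. With the libraries of each population summed, 865 genes were called, and 32 of the 44 called genes named here or in the closing section were called, while Cop1, Isg15, Tfap2c, Cxcr3, Parp14, Irgm1, Gbp3, B2m, C3, Mmp3, Postn and Odc1 were not.

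Cop1 loss under IFNγ was marked by lower interferon-stimulated, NF-kB target and chemokine transcripts and by higher MHC class II transcripts. Cxcl9 (chromosome 5, 92321347 to 92328079), a CXCR3 ligand, stood at 301 ± 4.97 CPM in treated Rosa26 cells and at 141 ± 4.88 and 149 ± 7.10 in treated sgRNA1 and sgRNA2 cells (SD, n = 2), a log2 change of -1.05 ± 0.04. Ptgs2 stood at 1070 ± 4.10 CPM in treated Rosa26 cells against 502 ± 5.95 and 489 ± 2.91, a change of -1.11 ± 0.02. Cd74, the MHC class II invariant chain, was higher, at 65.2 ± 2.88 CPM in Rosa26 cells against 127 ± 3.52 and 103 ± 3.33, a change of 0.81 ± 0.05. The immediate early gene Egr1 (chromosome 18, 34859823 to 34864984) was lower by -1.51 ± 0.06. In edgeR's test 4828 of 11904 genes were called (2362 higher, 2466 lower), 282 of them at least 2-fold.

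Under IFNγ, 21 of 23 type I interferon-stimulated genes were lower in Cop1-loss cells (21 adjusted over the list alone; camera, adjusted p = 2.58e-22, and adjusted p = 0.000582 with an estimated correlation), with Ifit1 at -1.79 ± 0.09 and Rsad2, which encodes the antiviral protein viperin, at -2.08 ± 0.12. All 4 tested among 11 listed CXCR3 ligands and lymphocyte chemokines were lower (4 adjusted over the list alone; camera, adjusted p = 1.43e-22, and adjusted p = 0.000582 with an estimated correlation), among them Cxcl10 (-0.79 ± 0.05) and Cxcl16 (-0.93 ± 0.03). Of 18 IFN signalling and feedback genes, 3 were higher and 8 lower (3 and 8 adjusted over the list alone; camera, adjusted p = 0.0537), including Irf7 (-0.91 ± 0.07) and the ISG15 protease Usp18 (-1.10 ± 0.11). Without Rosa26 IFNγ replicate 1, or without replicate 2, 7 of the 18 were called. Guanylate-binding proteins and immunity GTPases did not share this direction, with 4 higher and 1 lower of 16 (4 and 1 adjusted over the list alone; camera, adjusted p = 0.0683). Of 11 MHC class II genes, 8 were higher (8 adjusted over the list alone; camera, adjusted p = 8.73e-06). Of these, H2-Eb1 had 0 counts in every vehicle library and 4.58 ± 1.13 CPM in treated Rosa26 cells against 14.7 ± 0.507 and 10.3 ± 0.459 (SD, n = 2). BALB/c cells carry other H2 alleles than the reference genome, so H2 levels depend on how well their reads aligned. Of 19 MHC class I presentation genes, 11 were higher and 3 lower (11 and 3 adjusted over the list alone; camera, adjusted p = 0.0154, and adjusted p = 0.162 with an estimated correlation), with the proteasome genes Psme2 (0.31 ± 0.03) and Psmb8 (0.32 ± 0.04) among the higher ones.

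Of 23 NF-kB targets, 21 were lower in treated Cop1-loss cells (21 adjusted over the list alone; camera, adjusted p = 1.22e-16), for example Nfkb2 (-0.38 ± 0.03) and Ccl20 (-1.82 ± 0.14). Of 9 neutrophil attractants, 6 were lower (8 adjusted over the list alone; camera, adjusted p = 2.46e-19), with Cxcl5 at -1.23 ± 0.02, Cxcl3 at -1.65 ± 0.08 and Cxcl1 (chromosome 5, 90891241 to 90893115) at -0.56 ± 0.03. Of 13 monocyte and macrophage attractants, 9 were lower and 2 higher (9 and 2 adjusted over the list alone; camera, adjusted p = 0.00146). Ccl2 was lower (-0.58 ± 0.12, adjusted p = 0.00709), a call that ended without Rosa26 IFNγ replicate 1 (adjusted p = 0.0545), with 1.56e-17 to 1 over all alternatives. Csf1 was lower by -0.20 ± 0.03 and Cx3cl1 higher by 0.95 ± 0.04. Of 13 checkpoint and immune-evasion genes, 3 were higher and 6 lower (3 and 6 adjusted over the list alone; camera, adjusted p = 0.00052), including Nos2 (-0.61 ± 0.03). The leukocyte markers Cd14 (-0.60 ± 0.09) and Cd68 (-0.60 ± 0.12) were lower too, as 2 of the 4 tested among 18 on that list (3 adjusted over the list alone; camera, adjusted p = 0.107).

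Of 14 C/EBP and acute-phase genes, 8 were lower and 1 higher in treated Cop1-loss cells (9 and 1 adjusted over the list alone; camera, adjusted p = 5.08e-09), with Cebpd at -1.24 ± 0.07, Cebpb at -0.82 ± 0.05 and Steap4 at -1.48 ± 0.10. Of 21 genes of the integrated stress response and unfolded protein response, 15 were lower and 4 higher (15 and 4 adjusted over the list alone; camera, adjusted p = 4.27e-14). Ddit3, which encodes the stress factor CHOP (-1.81 ± 0.11), and Atf4 (-0.69 ± 0.03) were among the lower ones. Of 14 handling stress and immediate early genes, 3 of them heat-shock genes, 9 were lower and 2 higher (10 and 2 adjusted over the list alone; camera, adjusted p = 2.78e-19), including Atf3 (-1.71 ± 0.05) and Junb (-0.97 ± 0.03). AP-1 members and targets went both ways, 9 higher and 7 lower of 22 (9 and 7 adjusted over the list alone; camera, adjusted p = 0.946). Their median log2 change was 0.11 and their mean -0.12, with Plau at 1.55 ± 0.03 and Jun at -0.26 ± 0.04. ERK and ETS output had 7 higher and 7 lower of 23 (8 and 9 adjusted over the list alone; camera, adjusted p = 0.574), with a median of 0.07, a mean of -0.05 and Dusp6 at 0.57 ± 0.03. COP1 substrates, adaptors and partners had 7 higher and 9 lower of 25 (7 and 11 adjusted over the list alone; camera, adjusted p = 0.0174, and adjusted p = 0.053 with an estimated correlation), with Trib2 at 0.96 ± 0.08 and Ets2 at -0.82 ± 0.04. Large increases outside the lists were those of Tfap2c (2.33 ± 0.14), Cxcr3 (2.02 ± 0.13), Adgrg3 (1.75 ± 0.10) and Eya2 (1.30 ± 0.10). Of 28 lists, camera called 16 under IFNγ, and 13 held with an estimated correlation. After summing the libraries of each population, 1397 genes were called, with 41 of 46 named ones among them and Cop1, Rsad2, Irf7, Cxcl1 and Csf1 not.

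**Figure D2:**
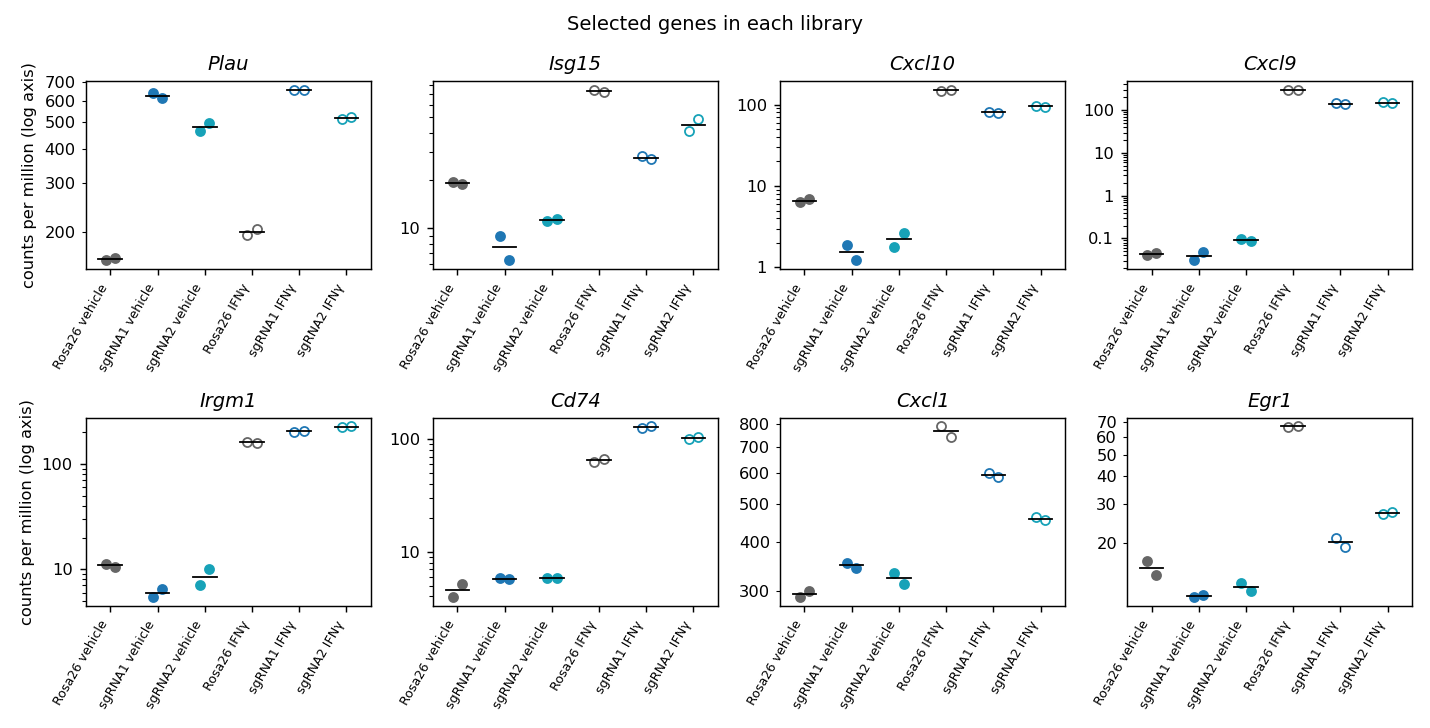
Expression of 8 genes in CPM (vertical log axes) in each library; points are libraries, filled for vehicle and open for IFNγ, and bars the means of 2. Cxcl10 and Isg15 were lower in Cop1-guide cells in both treatments, and Cd74 with IFNγ stood at 65.2 in Rosa26 cells against 127 and 103 in sgRNA1 and sgRNA2 cells.

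The changes with Cop1 loss were shared between treatments to a large degree. Across 11904 genes, the log2 changes in vehicle and with IFNγ, which share no library, had a Pearson correlation of 0.64 (Spearman 0.65), where genes are not independent replicates. Both comparisons use the same Rosa26 and guide populations, so a population difference unrelated to Cop1 would recur in both treatments. Cxcl10, Cebpd and Chac1 were lower and Plau, Tfap2c and Cxcr3 higher in both. Of 2983 genes called in both treatments, 2924 changed in the same direction, 1418 higher against 392 expected for independent lists and 1506 lower against 473 expected, and 59 in opposite directions. Without a low-count filter, over 16440 genes, the correlation was 0.16. Between guides within a treatment it was 0.75 in vehicle and 0.78 with IFNγ, where unchanged groups compared with the same Rosa26 libraries gave 0.51 and 0.49 in 20 simulations each. The covariance was 0.136 in vehicle against 0.0213 simulated and 0.148 with IFNγ against 0.0216. With 1 Rosa26 library given to each guide, so that no library was shared, the covariance was 0.107 and 0.103 in vehicle and 0.117 with IFNγ in both assignments, and the correlation 0.51, 0.48 and 0.53. Between guides across treatments, also without a shared library, the correlation was 0.54 (sgRNA1 in vehicle, sgRNA2 with IFNγ) and 0.55 (sgRNA2 in vehicle, sgRNA1 with IFNγ). The Rosa26 population was the same in all of these comparisons, and the simulations held no difference between populations.

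IFNγ raised antigen presentation, antiviral and chemokine genes strongly in Rosa26 cells and lowered many mitosis genes slightly. The transcription factor gene Irf1 rose by 3.54 ± 0.04 on the log2 scale. Cd274 (chromosome 19, 29367455 to 29388095), which encodes the checkpoint ligand PD-L1, rose from 1.63 ± 0.226 to 39.6 ± 3.35 CPM (SD, n = 2), a change of 4.59 ± 0.14. Cxcl9 had 2 counts over both vehicle libraries and 301 ± 4.97 CPM with IFNγ, a ratio of 7000 with a 95% counting interval of 1940 to 57800. In edgeR's test 3900 genes were called (1972 higher, 1928 lower), and of those changed at least 2-fold 337 rose and 99 fell.

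All 19 MHC class I presentation genes rose in Rosa26 cells (19 adjusted over the list alone; camera, adjusted p = 4.49e-164, and adjusted p = 7.99e-06 with an estimated correlation), including the peptide transporter Tap1 (5.14 ± 0.05), Psmb10 (3.17 ± 0.04) and B2m (1.20 ± 0.03). So did all 16 guanylate-binding proteins and immunity GTPases (16 adjusted over the list alone), among them Gbp4 (8.09 ± 0.06) and Igtp (6.43 ± 0.06). The median of these GTPases was 6.16, or 5.99 with 2 members of at most 3 vehicle counts at their bound (camera, adjusted p = 2.41e-07 with an estimated correlation). All 23 type I interferon-stimulated genes rose as well (23 adjusted over the list alone; camera, adjusted p = 1.18e-72), among them Parp14 (3.81 ± 0.05). Of 11 MHC class II genes 9 rose (9 adjusted over the list alone; camera, adjusted p = 1.28e-13), with Cd74 at 3.85 ± 0.09, and of 18 IFN signalling genes 12 rose and 1 fell (12 and 2 adjusted over the list alone; camera, adjusted p = 6.15e-49), with Irf8 at 3.58 ± 0.05. Of 23 NF-kB targets 22 rose and 1 fell (22 and 1 adjusted over the list alone; camera, adjusted p = 2.94e-15), including the adhesion gene Icam1 (4.40 ± 0.13). Of 9 neutrophil attractants 7 rose (7 adjusted over the list alone; camera, adjusted p = 1.14e-17), with Cxcl1 at 1.38 ± 0.03 and Csf3 at 1.19 ± 0.03. Of 13 monocyte and macrophage attractants 9 rose and 3 fell (9 and 3 adjusted over the list alone; camera, adjusted p = 0.00154), with Ccl2 at 2.27 ± 0.16 and Csf1 at 0.81 ± 0.03. Of 4 tested CXCR3 ligands and lymphocyte chemokines 4 rose (4 adjusted over the list alone; camera, adjusted p = 8.09e-43), and of 13 checkpoint and immune-evasion genes 11 rose (11 adjusted over the list alone; camera, adjusted p = 5.59e-22), including Nos2 (4.23 ± 0.04).

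Handling stress and immediate early genes rose with IFNγ in Rosa26 cells, 10 of 14 with 1 lower (10 and 1 adjusted over the list alone; camera, adjusted p = 6.03e-11), including Egr1 (2.12 ± 0.08) and Atf3 (2.06 ± 0.06). Of the 3 heat-shock genes in the list 1 rose and 1 fell, and of the other 11 genes 9 rose. C/EBP and acute-phase genes rose in 10 of 14 (11 adjusted over the list alone; camera, adjusted p = 8.01e-10), with Lcn2, which encodes lipocalin-2, at 1.39 ± 0.04 and Cebpd at 1.14 ± 0.08. AP-1 members and targets rose in 14 of 22 and fell in 4 (15 and 5 adjusted over the list alone; camera, adjusted p = 8.76e-05), with Jun at 0.68 ± 0.05. ERK and ETS output rose in 9 of 23 and fell in 6 (10 and 6 adjusted over the list alone; camera, adjusted p = 0.0154). Integrated stress response genes rose in 16 of 21 (17 adjusted over the list alone, with 1 lower; camera, adjusted p = 0.00171, and adjusted p = 0.0697 with an estimated correlation). Of 24 mitosis genes 21 fell and 1 rose (23 and 1 adjusted over the list alone; camera, adjusted p = 4.27e-07), with Cdc20 at -0.63 ± 0.04 and the kinase Plk1 at -0.59 ± 0.04. Of 25 cholesterol and fatty acid synthesis genes 16 fell and 1 rose (17 and 1 adjusted over the list alone; camera, adjusted p = 0.00103), with the desaturase Scd2 at -0.51 ± 0.02. The largest decreases under the naming rule included Kank3 (-1.23 ± 0.08), Ephb6 (-1.17 ± 0.15) and Col6a1 (-1.12 ± 0.11). Camera called 17 of 28 lists, and 16 held with an estimated correlation. The division of calls moved with upper quartile scaling to 1605 higher and 2537 lower. Summed populations, which compare 1 Rosa26 column with 1 and take the spread from the guides, gave 1102 genes, without Cop1, Csf3 and Lcn2.

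In Cop1-loss cells IFNγ raised the same antigen presentation and antiviral lists. Irf1 rose by 3.60 ± 0.03 and Cd274 by 4.99 ± 0.10 on the log2 scale, averaged over the guides. Cxcl10 rose by 5.52 ± 0.07, from 1.55 ± 0.459 to 80.3 ± 1.34 CPM with sgRNA1 and from 2.21 ± 0.614 to 94.8 ± 0.265 CPM with sgRNA2 (SD, n = 2). Of 11904 genes 4073 were called (2152 higher, 1921 lower), and of those changed at least 2-fold 338 rose and 76 fell.

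All 19 MHC class I presentation genes (19 adjusted over the list alone), all 16 guanylate-binding proteins and immunity GTPases (16 adjusted over the list alone) and all 23 type I interferon-stimulated genes (23 adjusted over the list alone) rose in Cop1-loss cells, with Tap1 at 5.17 ± 0.04, Gbp4 at 8.93 ± 0.04 and Parp14 at 4.20 ± 0.04. Their medians were 2.02, 6.90 and 2.65 on the log2 scale, the same with members of at most 3 vehicle counts at their bounds (camera, adjusted p = 1.41e-212 for MHC class I and 1.28e-64 for type I genes, and for the GTPases adjusted p = 6.42e-05 with an estimated correlation). MHC class II genes rose in 9 of 11 (9 adjusted over the list alone; camera, adjusted p = 1.69e-24), with Cd74 at 4.30 ± 0.06, and IFN signalling genes in 15 of 18 with 1 lower (15 and 1 adjusted over the list alone; camera, adjusted p = 5.31e-50), with Irf8 at 2.64 ± 0.03. NF-kB targets rose in 14 of 23 and fell in 2 (16 and 3 adjusted over the list alone; camera, adjusted p = 1.42e-05), and neutrophil attractants in 7 of 9 (8 adjusted over the list alone; camera, adjusted p = 2.85e-08), with Cxcl1 at 0.63 ± 0.02. Handling stress and immediate early genes rose in 6 of 14 and fell in 2 (6 and 2 adjusted over the list alone; camera, adjusted p = 0.0577), with Egr1 at 0.96 ± 0.07 and Atf3 at 1.52 ± 0.05. Mitosis genes fell in 20 of 24 and rose in 2 (21 and 2 adjusted over the list alone; camera, adjusted p = 4.15e-05), with Cdc20 at -0.47 ± 0.03. Among the decreases under the naming rule were the Notch ligand Jag1 (-1.14 ± 0.04) and the matrix gene Npnt (-1.01 ± 0.06). Camera called 13 of 28 lists, and 11 held with an estimated correlation. With upper quartile scaling 1502 genes were higher and 3038 lower. The summed populations gave 1364 genes, among them all 14 named ones.

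**Figure D3:**
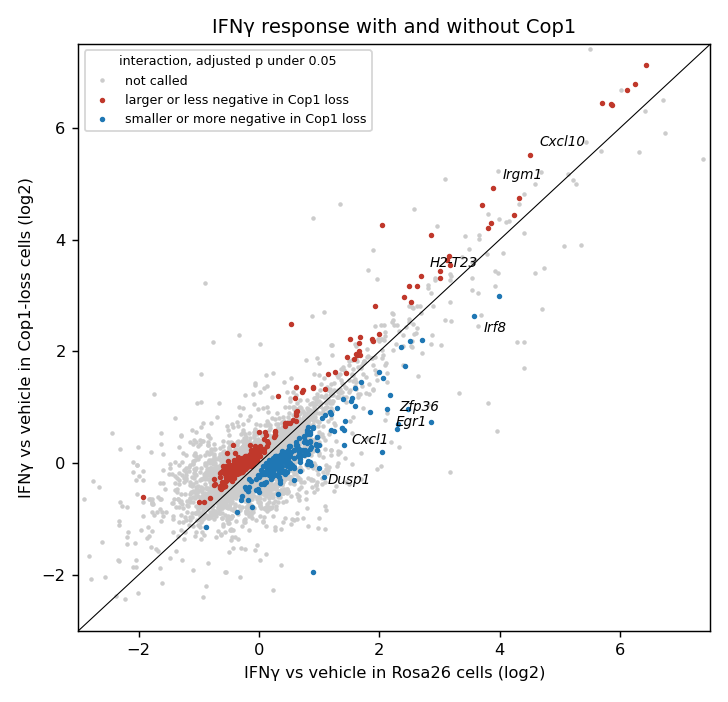
Log2 change with IFNγ in Cop1-loss cells (vertical axis) against that in Rosa26 cells (horizontal axis), 1 point per gene, with the line of equality; 35 genes lie outside the axes. Of the 683 genes whose responses differed, 402 are above the line, such as Irgm1 and Cxcl10, and 281 below it, such as Egr1 and Irf8.

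The response to IFNγ differed between Cop1-loss and Rosa26 cells for immunity GTPases and MHC class I genes, which responded more with Cop1 loss, and for immediate early, NF-kB and neutrophil chemokine genes, which responded less. For the GTPases the vehicle levels differed more than the treated ones. Of 16 tested, 11 were lower and 0 higher in Cop1-loss vehicle cells. With IFNγ 4 were higher and 1 lower than in Rosa26 cells, with a median log2 change of 0.02. Irgm1 (chromosome 11, 48861968 to 48871683), an immunity GTPase, responded more by 1.05 ± 0.10 on the log2 scale, from a lower vehicle level (5.93 ± 0.713 CPM with sgRNA1 and 8.50 ± 2.09 with sgRNA2 against 10.8 ± 0.666 in Rosa26; SD, n = 2) to a higher treated one (205 ± 1.79 and 228 ± 1.99 against 161 ± 1.23). Cxcl10 responded more by 1.01 ± 0.15 while its treated level stayed lower, at 80.3 ± 1.34 and 94.8 ± 0.265 against 151 ± 2.55 CPM. Egr1 responded less by -1.16 ± 0.11, reaching 20.1 ± 1.35 and 27.3 ± 0.273 against 67.0 ± 0.0999 CPM. The interaction test called 683 genes, 402 with a more positive and 281 with a more negative response in Cop1-loss cells. This division was 339 to 332 with upper quartile scaling and turned to 318 and 349 with a stricter low-count filter, 63 and 91 with the guides as 1 group, and 255 and 302 without Cop1_sgRNA2 IFNγ replicate 2. Of the 683, 69 differed at least 1.5-fold and 18 at least 2-fold. Among the 402, IFNγ raised 70 and lowered 98 with a call in both Rosa26 and Cop1-loss cells. Among the 281, it raised 119 and lowered 11 with a call in both. Most of these genes called in both thus had a weaker response with Cop1 loss.

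Of 16 guanylate-binding proteins and immunity GTPases, 9 had a more positive IFNγ response with Cop1 loss (11 adjusted over the list alone; camera, adjusted p = 5.98e-11), including Gbp3 (0.76 ± 0.10). Without Rosa26 vehicle replicate 1, or without replicate 2, 5 of these GTPases were called. Of 19 MHC class I presentation genes 9 had a more positive response (12 adjusted over the list alone, with 1 more negative; camera, adjusted p = 8.28e-10), with H2-T23 at 0.66 ± 0.07 and Tapbp at 0.35 ± 0.04. Tapbp started from a lower level in Cop1-loss vehicle cells (-0.39 against Rosa26). Against Rosa26, the list had 5 higher and 6 lower in vehicle and 11 higher and 3 lower with IFNγ. Of 25 cholesterol and fatty acid synthesis genes 9 had a more positive difference (14 adjusted over the list alone; camera, adjusted p = 7.11e-10), with Scd2 at 0.22 ± 0.03. Here it marked a smaller decrease. The list's median change with IFNγ was -0.19 in Rosa26 cells, where Scd2 was at -0.51, and -0.02 in Cop1-loss cells. More negative responses were called for 8 of 14 handling stress and immediate early genes, none of them a heat-shock gene (9 adjusted over the list alone; camera, adjusted p = 5.94e-32), with the phosphatase Dusp1 at -1.08 ± 0.11 and Zfp36, which destabilizes cytokine mRNAs, at -0.96 ± 0.11. They were called for 11 of 23 NF-kB targets (15 adjusted over the list alone; camera, adjusted p = 1.74e-22), with Tnfaip3 at -0.38 ± 0.04, and for 5 of 9 neutrophil attractants (5 adjusted over the list alone; camera, adjusted p = 4.92e-17), with Cxcl1 at -0.74 ± 0.04. AP-1 members and targets had 12 of 22 more negative (13 adjusted over the list alone, with 1 more positive; camera, adjusted p = 8.9e-21), with Jun at -0.60 ± 0.06 and Junb at -0.51 ± 0.04, and ERK and ETS output 8 of 23 (10 adjusted over the list alone, with 2 more positive; camera, adjusted p = 7.39e-08). For the AP-1 list the vehicle levels contributed. Against Rosa26, 12 of its members were higher and 4 lower in vehicle, and 9 higher and 7 lower with IFNγ. Jun was at 0.34 in vehicle and -0.26 with IFNγ. The lists with more negative responses share members, such as Junb and Atf3 on the AP-1 and immediate early lists, so their results are not separate evidence. Irf8 was at -0.94 ± 0.07, from 18.3 ± 0.936 CPM in Rosa26 vehicle cells against 39.9 ± 0.894 and 35.1 ± 2.14 in Cop1-loss vehicle cells (SD, n = 2) to 218 ± 4.30 against 241 ± 5.84 and 226 ± 6.14 with IFNγ. Type I interferon-stimulated genes had 2 more positive and 1 more negative of 23 (3 and 1 adjusted over the list alone; camera, adjusted p = 0.614). Camera called 11 of 28 lists, and 8 held with an estimated correlation. The count fell to 453 without Rosa26 vehicle replicate 1, 353 without Rosa26 vehicle replicate 2 and 348 without Rosa26 IFNγ replicate 1. With each population's libraries summed, edgeR called 0 genes. An unadjusted p under 0.05 was found for 546, less than the share of 0.05 of the 11904 tested that unchanged genes would give. On the separate libraries DESeq2 called 437 and limma-voom 644. Taking the guides as 1 group left 154 genes, and ended the calls of Irgm1, Gbp3 and Cxcl1.

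**Figure D4:**
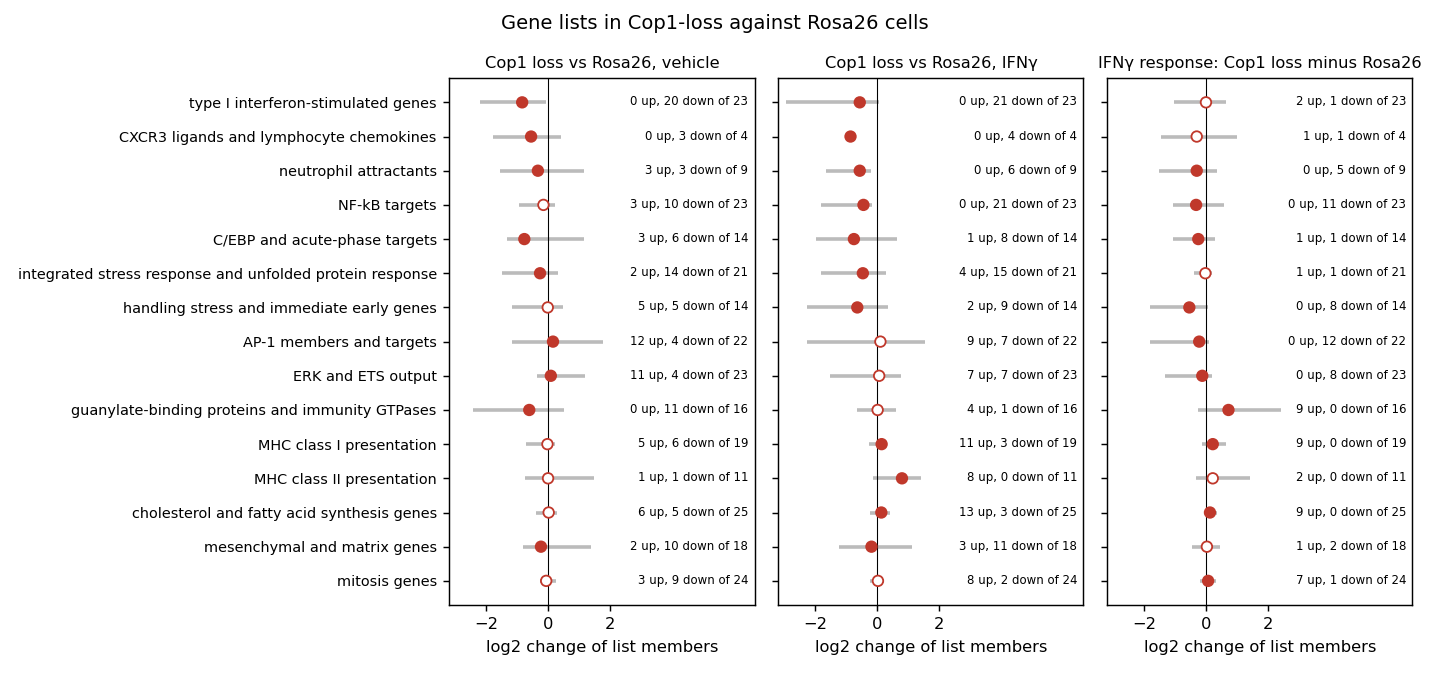
Median (points) and range (bars) of the log2 changes of 15 gene lists in 3 comparisons; filled points are lists called by camera with a preset correlation, and the text gives members called higher and lower of those tested. Type I interferon-stimulated genes were lower in vehicle (20 of 23) and with IFNγ (21 of 23). Of 14 handling stress and immediate early genes, 8 responded less to IFNγ with Cop1 loss, none of them a heat-shock gene.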

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

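Tests of carry-over, of single libraries and of drift were chosen only after the result was seen, while the heat-shock test was set beforehand. Groups of 2 libraries were too small for a test of outlying libraries. The responses to IFNγ stood out because the test of their difference between Cop1-loss and Rosa26 cells called 683 genes. Among the genes named by the rule, the response of Cop1-loss cells was above that of Rosa26 cells by 1.05 for Irgm1, 1.01 for Cxcl10, 0.76 for Gbp3, 0.66 for H2-T23, 0.35 for Tapbp and 0.22 for Scd2 on the log2 scale. The difference was negative for Tnfaip3 (-0.38), Junb (-0.51), Jun (-0.60), Cxcl1 (-0.74), Irf8 (-0.94), Zfp36 (-0.96), Dusp1 (-1.08) and Egr1 (-1.16).

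In vehicle, 31 genes of the type I interferon and immunity GTPase lists were lower in Cop1-loss cells, with a median log2 change of -0.83. Reads carried over from the treated Rosa26 libraries might raise such genes in Rosa26 vehicle libraries, but the largest carry-over that strongly induced genes allow, 0.052% of the treated level, accounts for 1.65% of the median gene's excess, and for over 50% in 1 of the 31. An effect of Cop1 loss on interferon signalling at rest, as a hypothesis, and a property of the single Rosa26 population unrelated to Cop1 both stay open.

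Immediate early genes responded less to IFNγ in Cop1-loss cells, with a median difference of -0.54 over the list of 14 handling stress and immediate early genes and -0.59 over the 11 of them that are not heat-shock genes. A heat-shock type stress at harvest of the treated Rosa26 cells would have raised heat-shock genes there, yet the median difference of 11 such genes, 3 of them from the list, was 0.02, with Dnajb1 lowest (-0.13) and Hspa8 highest (0.25). A single deviating library was not the source, as the median of the 14 stayed at or below -0.51 whichever of the 12 libraries was left out. Other differences in handling between treated Rosa26 and Cop1-loss cultures, and an effect of Cop1 loss on AP-1 and NF-kB dependent transcription, remain possible explanations that these libraries do not separate.

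The differences between Cop1-loss and Rosa26 cells were many and mostly small, with 4258 genes called in vehicle and 273 of them changed at least 2-fold. Drift of similar size in each of the 3 cell populations would have made the guides differ from each other about as much as from Rosa26, but the variance of guide-to-guide changes, less its error, was 0.19 of that between guide and Rosa26 with IFNγ and 0.18 in vehicle, over 9111 genes. Drift or handling of the 1 Rosa26 population cannot be told apart from loss of Cop1, since both would give changes shared by the guides, and the correlation between guides compared across treatments, without a shared library, was at least 0.54. The labels do not say whether the populations were pools or clones, and a further control population would be needed to separate these.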

How the results depend on the processing

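The sum over the libraries of each population was chosen only after the data were seen. Of 150 results for single genes, 0 changed direction under any alternative. Apart from the decreases of Cop1 with its guides, a called gene result failed to pass in 86 cases, counted per result and alternative, of which 47 were in the test against 1.5-fold, 32 with summed populations, 4 with the guides as 1 group and 3 on leaving out a library. Ccl2 in vehicle, which was not called, passed in 5 alternatives. In the test against 1.5-fold, 169 genes were called for Cop1 loss in vehicle, 192 with IFNγ, 423 for IFNγ in Rosa26 cells, 428 in Cop1-loss cells and 6 for the interaction, which follows from the stricter null. With summed populations these were 865, 1397, 1102, 1364 and 0, a test whose spread comes from the guides alone. There, 546 interaction genes had an unadjusted p under 0.05, less than the share of 0.05 of the 11904 tested that unchanged genes would give. Requiring each guide alone to call a gene left 2597 in vehicle and 2937 with IFNγ. For the interaction DESeq2 called 437 and limma-voom 644, and the guides as 1 group gave 154, and the cause was not tested. The decrease of Cop1 with the guides as 1 group was -0.96 in vehicle (adjusted p = 0.0644) and -0.80 with IFNγ (adjusted p = 0.108), because the guides differed in Cop1 level, and with summed populations -0.97 and -0.81, with adjusted p up to 0.342 and 0.395 over the alternatives.

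On leaving out each library in turn, the counts were 2919 to 4284 for Cop1 loss in vehicle, 3612 to 4950 with IFNγ, 2960 to 4056 for IFNγ in Rosa26 cells, 3505 to 4054 in Cop1-loss cells and 348 to 733 for the interaction. The lowest interaction counts came without Rosa26 vehicle replicate 1 (453), Rosa26 vehicle replicate 2 (353) and Rosa26 IFNγ replicate 1 (348). The correlation of Cop1-loss changes between treatments was 0.64, 0.16 without a low-count filter and 0.48 to 0.57 on leaving out a library. The set of genes changed too. It held 11904 genes in the main fit, 16440 without a filter and 12153 to 12180 on leaving out a library, where the filter was run again. The lower values therefore do not show dependence on single libraries apart from the added genes, and the cause was not tested. The division into higher and lower turned for Cop1 loss in vehicle with upper quartile scaling (2199 and 2112), for Cop1 loss with IFNγ in DESeq2 (1974 and 1915) and for IFNγ in Cop1-loss cells with a stricter filter (1964 and 2117). DESeq2 size factors changed no count by over 1.5 times. Of 3332 recounts of called list members over 140 lists and comparisons, 408 moved by over 1.5 times, 116 of them in the test against 1.5-fold and 105 with summed populations. With the replicate block, 4292, 4862, 3926, 4115 and 693 genes were called in the 5 comparisons, and 0 of the camera calls changed, at an adjusted p under 0.05 in both fits. The replicate numbers showed no pairing, as same-numbered deviations correlated between -0.05 and 0.07 over 15 pairs of groups. Depth limits genes such as Gbp5 and H2-Eb1, whose vehicle counts were close to or at 0.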

Other observations

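Some lists of cell-state genes outside the immune and COP1-related lists also differed with Cop1 loss. Of all genes tested, 35.8% were called for Cop1 loss in vehicle, 40.6% with IFNγ and 34.2% for IFNγ in Cop1-loss cells. Counts of called members near these shares do not set a list apart. Of 18 mesenchymal and matrix genes, 10 fell and 2 rose in vehicle (10 and 2 adjusted over the list alone; camera, adjusted p = 6.86e-06), and 11 were lower and 3 higher in treated Cop1-loss cells (11 and 4 adjusted over the list alone; camera, adjusted p = 4.99e-05). Thbs1, which encodes the matrix protein thrombospondin-1, fell by 0.81 ± 0.03 on the log2 scale in vehicle. Of 19 epithelial genes, 9 fell and 5 rose in vehicle (11 and 6 adjusted over the list alone; camera, adjusted p = 0.119), with the adhesion gene Cdh1 at -0.48 ± 0.02 and the keratins Krt18 and Krt8 at 0.25 ± 0.02 and 0.24 ± 0.02. Of 17 TGF-beta targets, 8 were lower and 5 higher in treated Cop1-loss cells (8 and 5 adjusted over the list alone; camera, adjusted p = 0.000183, and adjusted p = 0.0513 with an estimated correlation). Ccn2, a matricellular growth regulator, stood at -0.77 ± 0.05 against Rosa26 in vehicle and at -1.22 ± 0.05 with IFNγ.

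Of 20 MYC and ribosome biogenesis genes, 9 rose and 5 fell in vehicle (9 and 5 adjusted over the list alone; camera, adjusted p = 0.00417, and adjusted p = 0.125 with an estimated correlation), with Odc1, which starts polyamine synthesis, at 0.57 ± 0.02 (not called with summed populations) and Npm1 at 0.25 ± 0.02. Of 25 cholesterol and fatty acid synthesis genes, 13 were higher and 3 lower in treated Cop1-loss cells (14 and 4 adjusted over the list alone; camera, adjusted p = 0.000148). Of 18 p53 targets, 11 were lower and 2 higher in treated Cop1-loss cells (12 and 2 adjusted over the list alone; camera, adjusted p = 0.000886), including Plk2 (-1.12 ± 0.04), which was at -0.73 ± 0.04 in vehicle. Sesn2, a stress-induced p53 target, fell by 0.93 ± 0.13 in vehicle. Of 22 hypoxia and glycolysis genes, 7 were lower and 2 higher in treated Cop1-loss cells (7 and 2 adjusted over the list alone; camera, adjusted p = 0.162), with Vegfa at -0.68 ± 0.06 and Ndrg1 at -0.56 ± 0.03. Against treated Rosa26 cells, treated Cop1-loss cells had 8 of 24 mitosis genes higher and 2 lower (8 and 2 adjusted over the list alone; camera, adjusted p = 0.162). DNA replication genes rose with IFNγ in 12 of 25 in Cop1-loss cells (13 adjusted over the list alone; camera, adjusted p = 0.552). IFNγ in Rosa26 cells lowered Krt8 (-0.58 ± 0.03) and raised the hexokinase gene Hk2 (0.80 ± 0.04).

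A test set before its result was seen asked whether the size of the changes may follow the remaining Cop1 mRNA, which was lower with sgRNA2. Over 385 genes chosen from the IFNγ comparison, the median ratio of absolute log2 changes in vehicle, sgRNA2 over sgRNA1, was 0.87 (bootstrap 95% interval 0.84 to 0.90, over genes, which are not independent). In 67% of these genes the change was smaller with sgRNA2, so the predicted larger changes with more loss of mRNA were not seen between these populations. Each guide had a single population, and the interval does not measure the spread between populations. The comparison therefore cannot decide whether changes follow the Cop1 mRNA level. The protein left by each guide was not measured in these libraries.

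For IFNγ in Cop1-loss cells, 1 of the 35 splits of the 8 libraries into 4 and 4, the real one, called 2785 genes in a model without the guides, and the highest count of the others was 40, for the split by guide. Chance is excluded by this count only if every library is a separate sample. With the 2 libraries of each group kept together 3 splits exist, too few for a share under 0.05.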
